A study of Mus musculus with 12 samples.

How the data were processed

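Gene expression was measured in kidney tubules of 4 mice, 2 female (mice 1 and 3) and 2 male (mice 2 and 4). Per the series' design text, tubules in suspension were sorted with a COPAS instrument, a large-particle flow sorter, into tubules carrying the green fluorescent protein EGFP, which are distal convoluted tubules (DCT, the nephron segment after the thick ascending limb), tubules without it, and a total fraction. The fractions are called EGFP+, EGFP- and ALL here. Each of the 12 samples is 1 fraction of 1 mouse, so n = 4 mice per fraction. How the mice came to express EGFP, their age and their strain are not given in the sources used here. Per the labels, total RNA was isolated with an Ambion microRNA kit, amplified with Agilent's low-input linear kit and labelled with Cy3 for one-colour hybridisation.

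Per the file headers, the arrays are Agilent whole-genome arrays of design 014868, scanned and read with Feature Extraction 9.5.3.1. The deposited scanner values used here are the processed signal of each spot, an intensity on a linear scale that the software had already background-corrected, and its mean signal and local background, intensities as well. Each array held 45018 spots, of which 43379 were not controls and covered 41174 probes. The 75th percentile of the processed signal ran from 922 to 2270 over the 12 arrays, and between 53.9% and 65.6% of probes were well above background by the software's own call. The number of arrays limits the precision. The ALL and EGFP- arrays of mouse 4 were the dimmest, with 75th percentiles of 922 and 1007. No array had more than 2 saturated spots, and between 66 and 516 spots per array carried an outlier mark and were left out.

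A value table by the authors was deposited beside the scanner files. It holds intensities on a linear scale, rescaled so that the columns' upper quartiles lie between 1586 and 1644, by a method not given in the sources used here. The column medians for mice 1 to 4 were 140.7, 120.2, 125.6 and 109.8 under the heading EGFP+, 133.6, 121.8, 125.4 and 107.2 under ALL, and 110.0, 112.5, 107.5 and 108.3 under EGFP-. Of its 41267 probes, 41174 were found in the scanner files. Each of the 12 columns matched the scanner file of another fraction of the same mouse, with a correlation across probes of at least 0.99999 on the log2 scale, and no column matched the file of its own heading. The column headed EGFP+ held the ALL array, the one headed ALL held the EGFP- array, and the one headed EGFP- held the EGFP+ array, in every mouse. All values in the report therefore come from the scanner files under their own labels. The table was used only as an alternative, once with its columns as headed and once matched by their values.

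The log2 processed signal of each array was scaled by subtracting its 75th percentile over non-control probes. All levels below are on this log2 scale, where 0 is an array's upper quartile. Spots of one probe were averaged. Probes well above background on at least 4 of the 12 arrays were tested, and each gene was represented by its tested probe with the highest mean over all arrays, which left 17071 genes. The level of one gene's probe is not compared with that of another gene's. Of the probes, 24375 were named through their accession, 6301 through a current symbol and 2426 through an older symbol in the reference table of mouse genes, and 8072 kept the name in the file. Of 6103 genes with more than 1 tested probe, 49 had the representative and a further probe both past the threshold in opposite directions for EGFP+ against EGFP-. Genes whose representative was not past the threshold are not in this count. Coordinates are those of the probes in the mm8 (NCBI36) mouse genome, per the file headers, and no annotation of that build was used.

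Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 and the package data.table (version 1.17.8). One coefficient was fitted per fraction over all 12 arrays, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Errors given with a difference are standard errors (SE) from this fit, and errors given with a level are standard deviations (SD) over the 4 mice. Where no probe of a gene was well above background on any array of the dimmer fraction, the fold is a lower bound. It sets the brighter fraction's mean against the mean, over the dim fraction's arrays, of the higher of the lowest signal well above background on that array and the probe's own signal. Sex was tested on the mean of each mouse's fractions, 2 males against 2 females. The dependence of the EGFP+ against EGFP- difference on sex was tested on the 4 per-mouse differences. Sex within a fraction was tested with 6 groups of 2 arrays. Between the sexes the same bound was used where the gene's own probe was not well above background on any array of the dimmer sex. Because of the spots left out, 445 of the 17071 genes lack a value on at least 1 array, 382 of them among the 1707 brightest, with 349 missing on the ALL and 157 on the EGFP- array of mouse 2. For 391 genes the sex comparison therefore has no value for mouse 2 and for 89 none for another mouse, and 11 of those past the threshold rest on 1 male. The tests on mouse means left out 1 gene.

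Fractions with the same number come from the same mouse. Their deviations from the fraction means correlated across genes in every pair, with r from 0.23 to 0.35 for EGFP+ with EGFP-, 0.30 to 0.39 for EGFP+ with ALL and 0.72 to 0.82 for ALL with EGFP-, and each array correlated best with its own mouse. The fit with the mouse as a block was an alternative. The arrays lay on 3 slides, each with arrays of all 3 fractions, and were scanned on 2 days. Slide 1 held all 3 fractions of mouse 1 and EGFP+ of mouse 2, slide 2 held ALL and EGFP- of mouse 2 with EGFP+ and ALL of mouse 3, and slide 3 held EGFP- of mouse 3 with all 3 fractions of mouse 4. Each slide was scanned in 1 session, so scan and slide are the same batch.

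Before the data were examined, 24 gene lists, the main fits, most alternatives and the rule for naming genes were fixed. The lists cover DCT salt and magnesium handling, late DCT and connecting tubule calcium handling, collecting duct principal cells, intercalated cells, thick ascending limb, proximal tubule, podocytes, endothelium, smooth muscle and stroma, leukocytes, erythroid cells, immediate early and heat shock genes, tubular injury, oxidative phosphorylation and citrate cycle, glycolysis, fatty acid oxidation, gluconeogenesis and fructose use, drug and organic ion handling, the aldosterone and epithelial sodium channel pathway, protein phosphatase subunits and inhibitors, nephron transcription factors, male-higher and female-higher kidney genes, and Y-linked genes. They hold 330 different genes on the array, 27 of them in more than 1 list, and 5 listed genes were not found. Lists were tested with limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison, on members with a value on all 12 arrays. That left 23 of 39 proximal tubule genes, 9 of 26 of oxidative phosphorylation and citrate cycle, 8 of 15 of glycolysis, 8 of 19 of fatty acid oxidation, 4 of 7 of gluconeogenesis and fructose use, 14 of 20 of drug and organic ion handling, 6 of 10 male-higher and 4 of 5 female-higher genes. It also left 20 of 24 of DCT salt and magnesium handling, 6 of 8 of late DCT and connecting tubule calcium handling, 11 of 12 of thick ascending limb, 10 of 11 of the aldosterone pathway and all members of the other lists. Medians and counts cover all tested members. An alternative chosen after the results were seen ran camera on the moderated t of all tested members. Camera asks whether a list's genes moved more than other genes.

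The rule names, for EGFP+ against EGFP-, the 12 genes higher and the 12 lower with the largest difference among those past the threshold, with the same sign in all 4 mice, a gene symbol other than a clone or prediction, and a probe well above background on at least 3 of 4 arrays of both fractions, and the 5 higher and 5 lower by the bound. It names 5 higher and 5 lower for the other fraction comparisons and for sex, the Y-linked genes and Xist, up to 5 for the dependence on sex, 3 members of each list past the threshold, and Slc12a3, Pvalb, Ppp1r1a, Trpm6, Calb1, Slc12a1, Umod, Aqp2, Slc34a1 and Lrp2 always. Some members of the lists are not reported here by name, though they count in the lists' tests. Members of lists named beyond the 3, and the probes of Wnk1, were chosen after their values were seen.

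Apart from the share, the steps were tested on simulated data with the arrays' own spread, the gene tests with 50 genes changed at each size. For EGFP+ against EGFP- without a block, 15 of 50 genes changed 1.5-fold were found, 31 changed 2-fold, 45 changed 4-fold and 49 changed 8-fold, with 3 false calls among 143. With the mouse as a block they were 18, 31, 48 and 49, with 11 false calls among 157 (7.01%). A single simulated data set cannot tell this from the 5% of the threshold. For male against female mice, 0 of 50 were found at 1.5-fold, 0 at 2-fold, 17 at 4-fold and 36 at 8-fold. For the dependence of the fraction difference on sex, 0 of 50 were found at each of these sizes, so that a count of 0 there carries no weight. For EGFP+ against EGFP-, camera found the 1 shifted list and called 0 others, in data drawn without correlation between genes. It cannot show how camera behaves on correlated lists, such as podocytes (estimated correlation 0.70) and endothelium (0.82) in this comparison. For the share, each ALL array was an exact mix of its mouse's EGFP+ and EGFP- arrays without added spread. A true share of 10% was returned as 10% by construction, which does not measure its precision.

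Alternatives changed 1 choice at a time, except normexp with quantile normalization, the mouse and slide together, and the fits of sex with 6 groups, which changed 2 together: the mouse, the slide or both as blocks, sex as a covariate, normexp background correction (offset 50) with quantile normalization, quantile normalization, median centring, no filter on dim probes or a filter on all 12 arrays, other rules for several probes of a gene, a fit on the fractions compared alone, an intensity trend, a 2-fold minimum, the authors' value table, and leaving out each mouse and each array. A random mouse block was fitted for the tests of sex.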

Results

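Tubules of the distal convoluted segment were compared with the other tubules of the same kidneys and with the total fraction, to find the genes enriched in that segment. In EGFP+ tubules Slc12a3, the thiazide-sensitive sodium chloride cotransporter that defines the DCT, was 331-fold higher than in EGFP- tubules (95% confidence interval 212 to 515). Its levels were 7.52 ± 0.23 in EGFP+, 4.51 ± 0.34 in ALL and -0.85 ± 0.66 in EGFP- tubules (SD, n = 4 mice), and its probe lies at 97240865 to 97240924 on chromosome 8. Pvalb, the calcium-binding protein parvalbumin of the early DCT, was at least 781-fold higher, with a level of 4.36 ± 0.20 in EGFP+ tubules and no EGFP- array well above background (probe at 78018472 to 78018531 on chromosome 15). Trpm6, the apical magnesium channel, was 271-fold higher and well above background on only 2 of 4 EGFP- arrays (18944659 to 18944718 on chromosome 19). Ppp1r1a, an inhibitor of protein phosphatase 1, was 32.9-fold higher, at 7.10 ± 0.08 in EGFP+, 4.47 ± 0.13 in ALL and 2.06 ± 0.26 in EGFP- tubules (103359427 to 103359486 on chromosome 15). Calb1, the calcium-binding protein calbindin of the late DCT and connecting tubule, was at least 9.18-fold higher, with 1 of 4 EGFP+ arrays saturated.

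**Figure D1:**
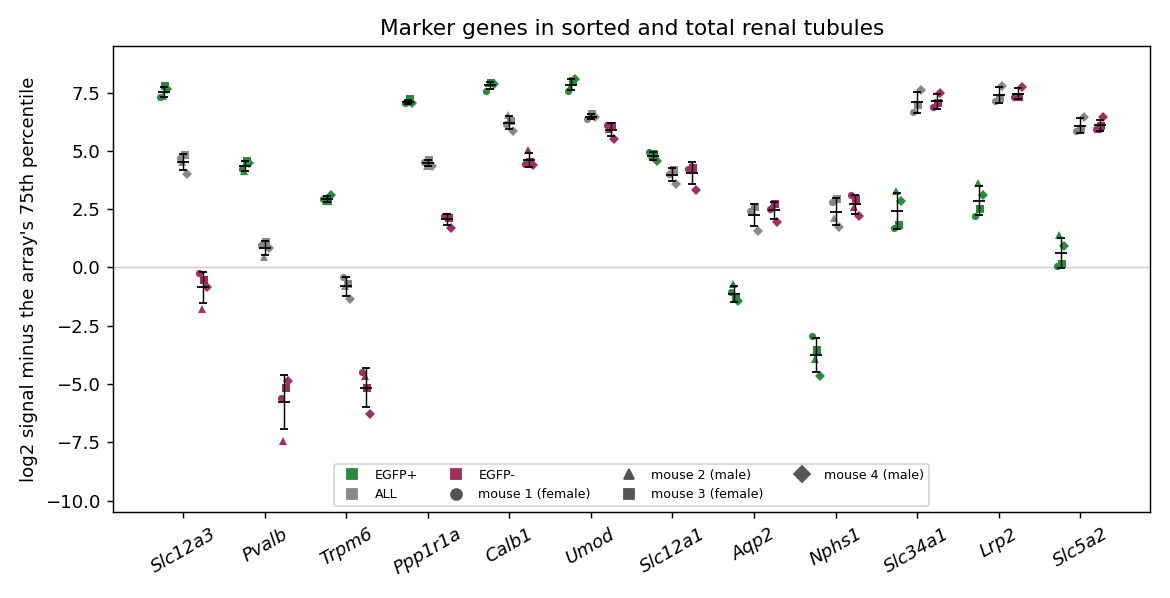
Log2 signal relative to each array's upper quartile for 12 genes of nephron segments, with a point per array, colour for the fraction, shape for the mouse, and the mean with its SD as bars. Slc12a3 was at 7.52 in EGFP+ and -0.85 in EGFP- tubules, while Slc34a1 was at 2.41 and 7.13.

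Of 17071 genes tested, 9932 (58.2%) differed between EGFP+ and EGFP- tubules in the limma fit, 5518 higher and 4414 lower in EGFP+. The larger differences lay on the lower side, with 892 genes at least 4-fold higher and 2236 at least 4-fold lower. The median difference of all genes was 0.11, and centring the arrays on their medians moved it to 0.26, with 62.7% of calls higher in place of 55.6%. Of the genes past the threshold, 9750 (99.1%) had the same sign within all 3 slides, in arrays that are part of the fit. Within slide 2 the EGFP+ array is of a female and the EGFP- array of a male mouse, so its differences mix sex with fraction. Slides 1 and 3 do so in part. Slide 1 sets EGFP+ arrays of a female and a male mouse against the EGFP- array of the female mouse. Slide 3 sets the EGFP+ array of a male mouse against EGFP- arrays of a female and a male mouse. With slide as a block, 10157 genes passed. Slc12a3 differed by 7.58, 9.54 and 8.34 within slides 1, 2 and 3 against 8.37 ± 0.29 (SE) pooled. The first principal component, with 79.5% of the variance, set the EGFP+ arrays apart from the others, and on the second, with 9.5%, females were positive and males negative in every fraction.

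The genes with the largest excess in EGFP+ tubules, among those well above background on at least 3 of 4 arrays of both fractions, included beside Slc12a3 several regulators of transcription. Sall3, a zinc finger factor, was 180-fold higher (7.49 ± 0.28, adjusted p = 2.2e-09), Prox1, a homeobox factor, 104-fold, and Batf3, a basic leucine zipper factor, 58.7-fold. Sfrp1, a secreted antagonist of Wnt signalling, was 79.2-fold higher, and Ptgfr, the receptor for prostaglandin F, 54.5-fold. Abca13, a transporter of the ATP-binding cassette family, was 93.7-fold higher, Cwh43 92.4-fold, Prom2 60.3-fold, Perm1, a muscle regulator of mitochondrial genes, 57.6-fold, Vstm2a 57.5-fold and Uroc1, an enzyme of histidine breakdown, 47.7-fold. Among genes not well above background on any EGFP- array, Sox9, a developmental transcription factor, was at least 111-fold higher, Hmgcll1, an enzyme related to that of ketone body synthesis, at least 102-fold, Ank2, a membrane adaptor, at least 68.1-fold and Mapk10, the neuronal form of Jun kinase, at least 60.3-fold. All of these were higher in 4 of 4 mice.

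The largest deficits, under the same condition, included several genes expressed in the glomerulus. Ptpro, a receptor phosphatase of podocytes, was 110-fold lower (-6.78 ± 0.50, adjusted p = 3.1e-07), Nphs1, which encodes the slit diaphragm protein nephrin, 88.5-fold and Synpo, which encodes synaptopodin, 75.1-fold. Itga8, an integrin chain of mesangial cells, was 83.7-fold lower, Gja5, a connexin of arterial endothelium and renin cells, 82.0-fold, and Plat, tissue plasminogen activator, 65.2-fold. Shisa3 was 100.5-fold lower, Sfrp2 97.4-fold, Myom2 91.5-fold, Chst1 85.2-fold, Ablim3 75.9-fold and Sulf1, a sulfatase of heparan sulfate, 68.7-fold. Where no EGFP+ array was well above background, Rarres1 was at least 42.1-fold lower, Papss2, which makes the sulfate donor of the cell, at least 37.4-fold, Ggt5 at least 37.3-fold, Nebl at least 36.4-fold and the immunoglobulin heavy chain probe Igh at least 35.3-fold. All of these were lower in 4 of 4 mice.

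Genes of salt and magnesium handling in the DCT were higher together in EGFP+ tubules. Of 24 tested, 19 were higher, 1 lower and 4 not past the threshold (19 and 1 adjusted over the list alone), and the list's median was 3.40 (3.45, 3.45 and 3.59 within slides 1, 2 and 3). Camera's adjusted p was 3.8e-09 and its adjusted p with an estimated correlation 0.0436. Beyond the transporters above they included Klhl3 (5.22), an adaptor of ubiquitin ligase that controls WNK kinases, Kcnj10 (4.16), the basolateral potassium channel, Emx1 (3.96), a homeobox factor, and Egf (3.13). Of 8 genes of late DCT and connecting tubule calcium handling, all 8 were higher (8 adjusted over the list alone), with a median of 2.41 (2.28, 2.62 and 2.53 within slides). Camera's adjusted p was 0.00178, and 0.149 as adjusted p with an estimated correlation. Trpv6 (4.07) and Trpv5 (2.99), the apical calcium channels, and Slc8a1 (4.00), the sodium calcium exchanger, were among them.

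Neighbouring segments gave mixed lists. Of 12 thick ascending limb genes, 8 were higher, 3 lower and 1 not past the threshold (8 and 3 adjusted over the list alone), with a median of 1.38 (1.10, 1.14 and 1.81 within slides). The list did not pass camera (adjusted p = 0.129, and adjusted p = 0.549 with an estimated correlation), but did with no filter on dim probes (adjusted p = 0.0493, with a range of 0.0493 to 0.164 over the alternatives). Casr, the calcium-sensing receptor, was higher by 4.20, Sostdc1, a secreted antagonist of bone morphogenetic proteins, by 3.62 and Umod, which encodes uromodulin, by 1.93 ± 0.16, while Cldn10, a tight junction protein of this limb, was lower (-5.05). Slc12a1, the furosemide-sensitive cotransporter, was 1.69-fold higher (adjusted p = 0.0125), and not past the threshold without mouse 1 (adjusted p = 0.0580, with a range of 7.4e-04 to 0.0580 over the alternatives). Of 10 collecting duct principal cell genes, 3 were higher and 7 lower (3 and 7 adjusted over the list alone), with a median of -3.06 (-3.18, -2.63 and -3.60 within slides, and -2.27 with genes at their bound). Camera's adjusted p was 0.0217, and 0.422 as adjusted p with an estimated correlation. The water channels Aqp2 (-3.59 ± 0.26) and Aqp3 (-3.73) and the sodium pump regulator Fxyd4 (-4.33) were lower, Aqp4 was at least 4.53-fold lower, and the sodium channel subunits Scnn1b and Scnn1g and the factor Gata3 were higher. Of 18 intercalated cell genes, 5 were higher, 6 lower and 7 not past the threshold (5 and 6 adjusted over the list alone), with a median of -0.20 (-0.13, 0.07 and -0.37 within slides), a mean of 0.01, a camera adjusted p of 0.8005 and an adjusted p of 0.995 with an estimated correlation. Atp6v1b1, a proton pump subunit, was higher (2.01), as was Oxgr1 (1.54), the oxoglutarate receptor, and Hmx2, a homeobox factor, was lower (-1.76).

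Proximal tubule genes were lower together in EGFP+ tubules. Of 39 tested, 37 were lower, 0 higher and 2 not past the threshold (38 lower adjusted over the list alone), with a median of -4.78 (-4.43, -5.27 and -4.43 within slides). Camera's adjusted p on 23 of them was 3.7e-11, and 0.115 as adjusted p with an estimated correlation. The sodium phosphate cotransporter Slc34a1 was 26.3-fold lower, the endocytic receptor Lrp2 (megalin) 24.1-fold, the glucose cotransporter Slc5a2 44.3-fold, the lactate cotransporter Slc5a12 45.6-fold and the sulfate cotransporter Slc13a1 42.4-fold. The EGFP+ array of mouse 2 held more of this signal than the others: the 32 genes of the list measured on all EGFP+ and EGFP- arrays stood at 5.72% of their EGFP- level in mouse 2, against 2.62%, 2.29% and 3.76% in mice 1, 3 and 4. Drug and organic ion handling genes, which share members with that list, had 18 of 20 lower and 2 not past the threshold (19 adjusted over the list alone), a median of -5.04 (-4.20, -5.59 and -4.37 within slides), a camera adjusted p of 2.0e-05 and an adjusted p of 0.0914 with an estimated correlation. Cyp4a12a (-5.51), Slco1a1 (-5.50) and Abcc2 (-5.49) were lowest, and Slco1a1 was not past the threshold with the mean of its probes (adjusted p = 0.169, with a range of 9.3e-08 to 0.169 over the alternatives).

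Markers of other kidney cells were also lower. All 14 podocyte genes were lower (14 adjusted over the list alone), with a median of -5.84 (-5.85, -5.51 and -6.49 within slides, -5.73 with genes at their bound), a camera adjusted p of 3.4e-09 and an adjusted p of 0.217 with an estimated correlation. Wt1 (-7.05), a transcription factor of podocytes, was well above background on 2 of 4 EGFP+ arrays. Of 15 endothelial genes, 14 were lower and 1 not past the threshold (14 adjusted over the list alone), with a median of -2.96 (-3.31, -3.07 and -2.95 within slides), a camera adjusted p of 2.1e-08 and an adjusted p of 0.258 with an estimated correlation. The junction protein Cldn5 (-5.78), Ehd3 (-4.11) and the coreceptor Eng (-4.01) were among them. Of 14 smooth muscle and stroma genes, 11 were lower and 3 not past the threshold (11 adjusted over the list alone), with a median of -3.10 (-2.58, -3.14 and -3.46 within slides, -2.86 with genes at their bound), a camera adjusted p of 1.6e-05 and an adjusted p of 0.258 with an estimated correlation. The growth factor receptor Pdgfrb was lower (-5.03), Pdgfra at least 20.7-fold lower and Des, which encodes desmin, at least 9.91-fold lower.

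Of 16 leukocyte genes, 12 were lower, 1 higher and 3 not past the threshold (12 and 1 adjusted over the list alone), with a median of -1.94 (-2.42, -2.21 and -1.84 within slides, -1.69 with genes at their bound), a camera adjusted p of 0.00153 and an adjusted p of 0.395 with an estimated correlation. Lysozyme Lyz2 (-4.90) and Cd52 (-3.74, with 1 of 4 EGFP+ arrays well above background) were lower, Tyrobp, a signalling adaptor, was at least 8.98-fold lower, and Fcer1g, an immunoglobulin receptor chain, was the higher member (0.87). All 4 erythroid genes were lower (4 adjusted over the list alone), with a median of -5.38 (-5.58, -4.29 and -5.63 within slides, -4.33 with genes at their bound), a camera adjusted p of 0.00439 and an adjusted p of 0.171 with an estimated correlation. The globin genes Hbb-bt (-5.76) and Hba-a1 (-5.44) were lower, and Alas2, an enzyme of haem synthesis, at least 9.34-fold lower.

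**Figure D2:**
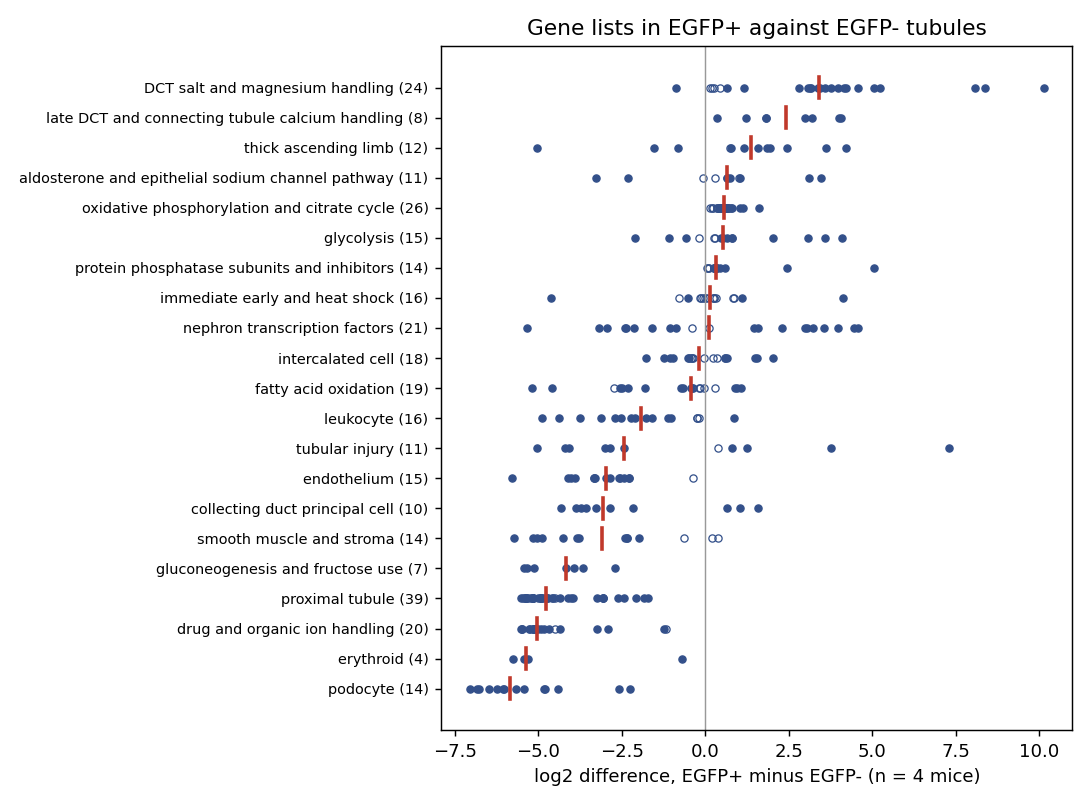
Log2 difference between EGFP+ and EGFP- tubules (x axis) for each tested member of 21 gene lists (y axis), filled where the adjusted p of the gene passed 0.05, with a red bar at the list's median. The medians ran from 3.40 for DCT salt and magnesium handling to -5.84 for podocytes.

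Genes of energy metabolism divided by pathway. Of 26 genes of oxidative phosphorylation and citrate cycle, 16 were higher and 10 not past the threshold (17 adjusted over the list alone), with a median of 0.56 (0.61, 0.77 and 0.49 within slides), a camera adjusted p of 0.00478 on 9 of them (median 0.72) and an adjusted p of 0.24 with an estimated correlation. Ppargc1a, a coactivator of mitochondrial biogenesis, was 3.05-fold higher (1.61 ± 0.13), Cox7b was higher by 1.11 and Idh3a by 1.04. Of 15 glycolytic genes, 8 were higher, 3 lower and 4 not past the threshold (9 and 3 adjusted over the list alone), with a median of 0.53 (0.51, 0.82 and 0.61 within slides). Camera, on the 8 of them with a value on all arrays (median 1.41), gave an adjusted p of 0.0363, and 0.434 as adjusted p with an estimated correlation. With all 15 it was 0.0591, not past the threshold. It was 0.0668 with the mouse as a block, 0.0592 with slide as a block, 0.0602 without mouse 2 and 0.0594 with quantile normalization, with a range of 0.00696 to 0.0815 over the alternatives. Pyruvate kinase Pkm (4.10), the phosphofructokinase Pfkp (3.58) and hexokinase Hk1 (3.08) were higher. All 7 genes of gluconeogenesis and fructose use were lower (7 adjusted over the list alone), with a median of -4.16 (-3.84, -4.67 and -4.18 within slides), a camera adjusted p of 9.1e-04 on 4 of them and an adjusted p of 0.171 with an estimated correlation. The fructose transporter Slc2a5 (-5.44), the glucose transporter Slc2a2 (-5.35) and glucose 6-phosphatase G6pc (-5.12) led them. Of 19 fatty acid oxidation genes, 3 were higher, 9 lower and 7 not past the threshold (3 and 9 adjusted over the list alone), with a median of -0.42 (-0.28, -0.62 and -0.53 within slides), a camera adjusted p of 0.642 on 8 of them and an adjusted p of 0.746 with an estimated correlation. The acyl-CoA synthetases Acsm1 (-5.18) and Acsm2 (-4.58) and the peroxisomal enzyme Ehhadh (-2.56) were lower.

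Of 14 protein phosphatase subunits and inhibitors, 6 were higher and 8 not past the threshold (6 adjusted over the list alone), with a median of 0.32 (0.36, 0.26 and 0.17 within slides). Camera's adjusted p was 0.0374, and 0.258 as adjusted p with an estimated correlation. It was 0.0609 without mouse 1, 0.0550 without mouse 2 and 0.0594 with quantile normalization, with a range of 0.0107 to 0.0609 over the alternatives. Ppp1r1a stood first, followed by its relative Ppp1r1b (2.44) and the calcineurin subunit Ppp3cb (0.58). Of 11 genes of the aldosterone and epithelial sodium channel pathway, 6 were higher, 2 lower and 3 not past the threshold (7 and 2 adjusted over the list alone), with a median of 0.65 (0.28, 0.49 and 1.04 within slides), a camera adjusted p of 0.467 and an adjusted p of 0.658 with an estimated correlation. The potassium channel Kcnj1 (3.46) and the sodium channel subunit Scnn1a (3.11) were higher, and Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids, was at least 5.13-fold lower. Of 21 nephron transcription factors, 10 were higher, 9 lower and 2 not past the threshold (10 and 9 adjusted over the list alone), with a median of 0.10 (0.25, 0.17 and -0.09 within slides), a camera adjusted p of 0.509 and an adjusted p of 0.541 with an estimated correlation. Tfap2b (4.57) and Esrrb (4.44) were higher and Hnf4a, a proximal tubule factor, lower (-5.35).

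Stress and injury genes showed no shared direction. Of 16 immediate early and heat shock genes, 2 were higher, 2 lower and 12 not past the threshold (1 and 1 adjusted over the list alone), with a median of 0.14 (-0.45, 0.42 and 0.34 within slides), a camera adjusted p of 0.992 and an adjusted p of 0.997 with an estimated correlation. Ier3 was higher by 4.13 and Myc lower (-4.63, with 2 of 4 EGFP+ arrays well above background), while Fos (1.08 ± 0.42, adjusted p = 0.0427) was not past the threshold without mouse 2, 3 or 4 (adjusted p = 0.0938, 0.113 and 0.153) or with slide as a block (0.0520), with a range of 2.6e-04 to 0.153 over the alternatives. Of 11 tubular injury genes, 4 were higher, 6 lower and 1 not past the threshold (4 and 6 adjusted over the list alone), with a median of -2.42 (-3.14, -2.18 and -1.94 within slides, -0.83 with genes at their bound), a camera adjusted p of 0.654 and an adjusted p of 0.772 with an estimated correlation. Sox9 was higher, and Havcr1, the kidney injury molecule, was lower (-5.03 ± 1.30), with 2 of 4 EGFP+ arrays well above background, as was Vcam1, an adhesion molecule (-4.20), with 1 of 4.

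Against the total fraction, the same kinds of genes stood out with smaller differences on the higher side. Slc12a3 was 8.06-fold higher in EGFP+ than in ALL tubules (3.01 ± 0.29, n = 4 mice). By the same rule, the 5 largest excesses were Sox9 (3.84), Ank2 (3.81), Grin3a, a glutamate receptor subunit (3.75), Trpm6 (3.74) and Hmgcll1 (3.73). The 5 largest deficits were Ptpro (-6.51), Shisa3 (-6.37), Sfrp2 (-6.35), Myom2 (-6.29) and Chst1 (-6.21). In all, 9434 genes differed, 5178 higher and 4256 lower, with 654 at least 4-fold higher and 2094 at least 4-fold lower. Of these, 9313 had the same sign within all 3 slides, in arrays that are part of the fit, and 9810 genes passed with slide as a block. Camera placed 5 lists higher and 10 lower, all 15 with the same sign within every slide, and 0 with an estimated correlation (lowest adjusted p = 0.0779, for DCT salt and magnesium handling). The median of the nephron transcription factors was -0.06 and their mean 0.12, and without mouse 1 the lists of collecting duct principal cells (adjusted p = 0.0529), glycolysis (0.0529) and protein phosphatases (0.0649) were not past the threshold, while the list of female-higher kidney genes was (0.0440). Quantile normalization ended the calls of glycolysis and protein phosphatases (0.0693 each). Glycolysis was not past the threshold with all members tested (0.0744), without mouse 2 (0.0766), with normexp and quantile normalization (0.104) or with the mouse as a block (0.0673), and the female-higher list was with the block (0.0135) and with all members (0.0353).

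Between ALL and EGFP- tubules nearly every difference was an excess in the total fraction, led by genes of the DCT. By the naming rule, which asks for probes well above background on at least 3 of 4 arrays of both fractions, these were the largest excesses. Slc12a3 was 41.0-fold higher in ALL (5.36 ± 0.29, adjusted p = 5.0e-06, higher in 4 of 4 mice), Sall3 by 3.76, Cwh43 by 3.21, Abca13 by 3.12 and Sfrp1 by 3.07. Of 238 genes that differed, 237 were higher in ALL, 47 of them at least 4-fold. All 238 had the same sign within the 3 slides, in arrays that are part of the fit. The lower gene was Dnajc14, a co-chaperone (-0.92 ± 0.13, adjusted p = 0.00348), which was not past the threshold with the mean of its probes (0.117) or without mouse 3 (0.102), with a range of 8.4e-04 to 0.117 over the alternatives. The count was 222 with slide as a block, 123, 92 and 99 without mouse 1, 2 or 3, and 158 and 154 without the ALL array of mouse 1 or 3. Of the DCT salt and magnesium genes, 12 of 24 were higher and 0 lower (15 adjusted over the list alone), with a median of 0.92 (0.93, 0.91 and 0.83 within slides), a camera adjusted p of 8.7e-49 and an adjusted p of 5.9e-05 with an estimated correlation. Of the late DCT and connecting tubule calcium genes, 4 of 8 were higher (6 adjusted over the list alone), with a median of 0.75 (0.59, 0.66 and 0.80 within slides), a camera adjusted p of 8.8e-09 and an adjusted p of 0.00834 with an estimated correlation. Of the nephron transcription factors, 4 of 21 were higher (6 adjusted over the list alone), with a median of 0.06 (0.20, 0.22 and 0.09 within slides), a mean of 0.30, a camera adjusted p of 1.2e-04 and an adjusted p of 0.00834 with an estimated correlation.

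A further 5 lists passed camera between ALL and EGFP- tubules, none of them with an estimated correlation. Glycolysis was higher (median 0.08, -0.02, 0.22 and 0.24 within slides, camera adjusted p = 2.1e-04 on 8 of 15 members with a median of 0.20, adjusted p = 0.405 with an estimated correlation). The lists of podocytes (-0.28, camera adjusted p = 8.4e-04), endothelium (-0.26, 2.0e-04), smooth muscle and stroma (-0.24, 8.4e-04) and proximal tubule (-0.12, 0.0306) were lower, each with an adjusted p of 0.602 with an estimated correlation and 0 members past the threshold. Within slides 1, 2 and 3 the medians were -0.21, 0.00 and -0.77 for podocytes, -0.21, -0.01 and -0.63 for endothelium, -0.08, -0.21 and -0.53 for smooth muscle and stroma, and -0.20, -0.03 and 0.26 for proximal tubule, whose adjusted p was 0.140 with slide as a block (0.00721 to 0.360 over the alternatives). Slide 2 sets ALL arrays of a male and a female mouse against the EGFP- array of the male mouse. Slide 3 sets the ALL array of a male mouse against EGFP- arrays of a female and a male mouse. The medians of slides 2 and 3 thus mix sex with fraction. Tubular injury genes had a median of -0.07 and a mean of 0.34, with a camera adjusted p of 0.0788. With slide as a block the lists of collecting duct principal cells (0.0141) and leukocytes (0.0192) passed, and with the mouse as a block those of thick ascending limb (0.0257, and 0.0142 with all members tested) and Y-linked genes (0.0181).

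The share of EGFP+ tubules that best placed the total fraction between the 2 sorted fractions was 14.5%, 9.51%, 11.2% and 4.46% in mice 1 to 4, with a mean of 9.91% ± 4.17 (SD, n = 4) over 3035 genes that differed at least 4-fold. It was 14.1% ± 1.86 over the 885 genes higher in EGFP+ tubules and 5.55% ± 5.99 over the 2150 lower ones. In mice 1 to 4 it was 15.3%, 15.3%, 14.4% and 11.4% over the higher genes. Over the lower genes it was 13.6%, 2.97%, 6.17% and -0.51%, the last of them negative. It is a share of signal, and no test was made of it.

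Tubules of male and female mice differed in genes of the sex chromosomes and in single genes of transport and metabolism. Averaged over the fractions of each mouse (n = 2 mice per sex), the Y-linked genes Eif2s3y (at least 185-fold), Ddx3y (at least 85.7-fold) and Kdm5d (at least 26.1-fold), with 0 of 6 female arrays well above background, were higher in males, and so was Uty, with 1 of 6. Xist, the transcript that silences the inactive X chromosome, was at least 525-fold lower in males and Tsix, its antisense transcript, at least 4.18-fold, with 0 of 6 male arrays well above background. The adjusted p was 6.0e-04 for Eif2s3y and 0.00123 for Xist. Slc7a13, an amino acid transporter of the proximal tubule, was higher in males by 8.77 ± 0.18 (SE), with 3 of 6 female arrays well above background, and Pzp, a protease inhibitor, was at least 32.4-fold higher. Slc7a12, a related transporter, was lower in males (-3.79), with 4 of 6 male arrays well above background, Prlr, the prolactin receptor, was lower as well (-3.58), and Ugt1a1, a glucuronidation enzyme, was at least 2.35-fold lower. In all, 217 genes differed, 165 higher and 52 lower in males, 11 of them resting on 1 male, and 3535 had an unadjusted p under 0.05. The count was 44, 23, 51 and 12 without mouse 1, 2, 3 and 4. Eif2s3y, Ddx3y, Kdm5d, Xist, Tsix, Slc7a13, Pzp and Cyp4b1 were past the threshold without each mouse in turn, while Uty, Slc7a12, Prlr, Ugt1a1, Acsm3, Cyp2e1, Abcc3, Havcr1 and Slco1a1 each were not without at least 1 mouse (adjusted p = 0.153 for Uty and 0.0535 for Slco1a1 without mouse 4). With normexp and quantile normalization the count was 933, of which 524 were higher and 409 lower.

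All 4 Y-linked genes were higher in males (4 adjusted over the list alone, fitted median 7.51 and 5.61 with 3 genes at their bound, camera adjusted p = 9.8e-09). Of 10 male-higher kidney genes, 5 were higher (9 adjusted over the list alone, median 2.07, camera adjusted p = 1.7e-05), led by Acsm3 (6.36) and Cyp2e1 (4.47), each resting on 1 male, and Cyp4b1 (4.09). Of 5 female-higher kidney genes, 3 were lower in males (4 adjusted over the list alone, median -2.59, camera adjusted p = 3.6e-05), with Abcc3, a drug exporter, at -1.95. With an estimated correlation each of these lists had an adjusted p of 0.562. Between EGFP+ and EGFP- tubules the male-higher list was lower in EGFP+ for 8 of 10 genes (9 adjusted over the list alone, median -3.17, camera adjusted p = 0.0129, adjusted p = 0.367 with an estimated correlation) and the female-higher list for 4 of 5 (4 adjusted over the list alone, median -4.94, camera adjusted p = 0.110, 0.0136 with the mouse as a block and 0.0353 with all members tested, adjusted p = 0.541 with an estimated correlation). The Y-linked list had 0 of 4 past the threshold there (0 adjusted over the list alone, median 0.18, camera adjusted p = 0.992, adjusted p = 0.997 with an estimated correlation). Within a slide these lists set a fraction of one sex partly against a fraction of the other, so no slide medians are given for them.

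Lists of cell types also differed by sex by camera with its preset correlation, though not with an estimated one. Of 39 proximal tubule genes, 6 were higher in males (18 adjusted over the list alone, median 0.59), with a camera adjusted p of 0.00131 on 23 of them (median 0.23). The lists of podocytes (median -0.77, 1.2e-05), endothelium (-0.45, 3.6e-05), leukocytes (-0.62, 0.00184) and immediate early and heat shock genes (-0.59, 0.00184) were lower in males by camera's adjusted p, with 0 members past the threshold over all genes. For each of these lists and for proximal tubule the adjusted p with an estimated correlation was 0.682. In EGFP- tubules the leukocyte genes' median deviation from the fraction's mean was 0.38 and 0.44 in the females, 0.08 in mouse 2 and -0.89 in mouse 4. For podocytes it was 0.40 and 0.28 in the females, -0.14 in mouse 2 and -0.45 in mouse 4. The ALL and EGFP- arrays of mouse 4 were the dimmest, and how much this adds to the differences was not tested. Camera placed 8 of 15 glycolytic genes, those with a value on all arrays, lower (median -0.36, adjusted p = 0.0180, and 0.682 as adjusted p with an estimated correlation). With all 15 (median 0.16) the adjusted p was 0.535. With all members the lists of oxidative phosphorylation and citrate cycle (0.00308), fatty acid oxidation (2.6e-04), gluconeogenesis and fructose use (0.00702) and drug and organic ion handling (0.00826) were higher in males, but 17 of 26, 11 of 19, 3 of 7 and 5 of 20 of their members lack a value for mouse 2. Of the tubular injury genes, Havcr1 was higher in males by 3.50 (11.3-fold), and of the drug and organic ion genes, 5 were higher, Slco1a1 (3.40) among them, and 3 lower.

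Within the fractions, 1273 genes differed by sex in EGFP- tubules (853 higher and 420 lower in males), 1620 in ALL (1130 and 490) and 172 in EGFP+ (150 and 22). The spread in this fit comes from all 6 groups, with no term for the mouse. The deviations of ALL and EGFP- correlated within a mouse (r from 0.72 to 0.82), so these counts may be too high. The simulation did not cover this fit. Degs2, a sphingolipid enzyme, differed by 3.74 in EGFP- and 3.45 in ALL but by -0.21 in EGFP+ tubules, and Prlr by -5.24, -5.01 and -0.50, while Cyp4b1 differed by 3.23, 3.39 and 5.65. Of these, Degs2 and Prlr passed in EGFP- and ALL but not in EGFP+ tubules (adjusted p = 0.873 and 0.999). Prlr was well above background on only 1 of 2 male EGFP+ arrays, so its difference there may be held down by the background. Pzp was at least 108-fold higher in males in EGFP-, at least 137-fold in ALL and at least 2.31-fold in EGFP+ tubules. In EGFP+ tubules the proximal tubule list's median was higher in both males than in both females, by 0.94. Each fraction had both sexes on 1 slide only. Of the genes past the threshold, all 1273 in EGFP- (slide 3), 1568 of 1568 measured in ALL (slide 2) and 172 of 172 in EGFP+ (slide 1) kept their sign there, in arrays that are part of the fit. With no filter on dim probes the counts were 576 in EGFP-, 705 in ALL and 116 in EGFP+. With slide as a block they were 1622, 1310 and 132. With normexp and quantile normalization they were 1856 in EGFP- (967 higher and 889 lower) and 2376 in ALL (1141 and 1235).

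**Figure D3:**
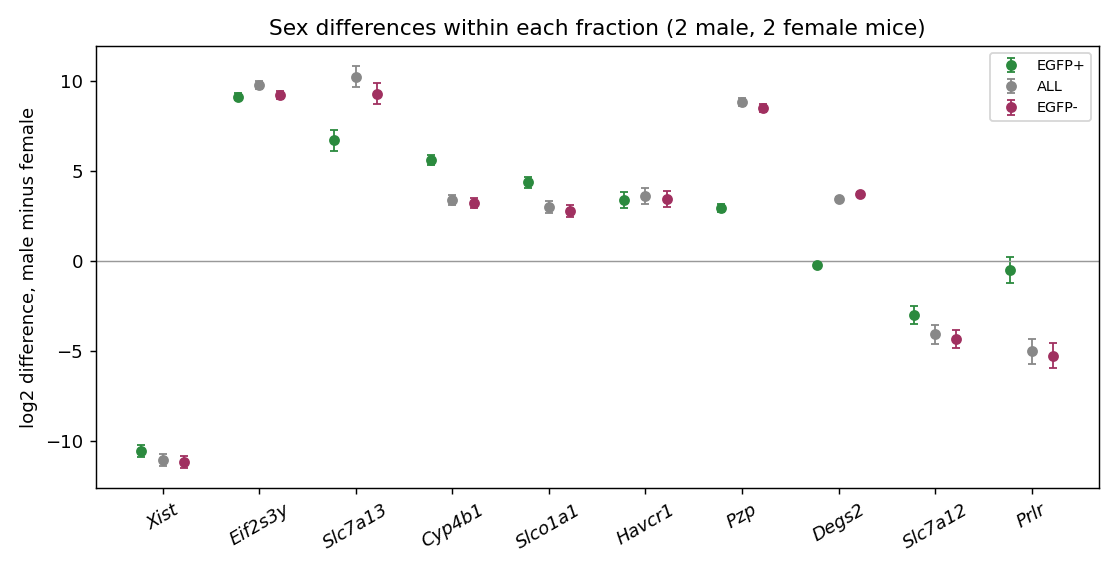
Log2 difference between males and females with its SE (y axis) for 10 genes (x axis) in EGFP+, ALL and EGFP- tubules, 2 mice per sex. Degs2 was at 3.74 in EGFP- and -0.21 in EGFP+ tubules, and the values drawn for Xist, Eif2s3y and Pzp rest on signals not above background in 1 sex. In EGFP+ tubules so do those for Slc7a13, Havcr1 and Slc7a12. Prlr had 1 of 2 male and Slco1a1 1 of 2 female EGFP+ arrays well above background.

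When the dependence of the EGFP+ against EGFP- difference on sex was itself tested, 0 genes passed in limma, with 2057 at an unadjusted p under 0.05. The smallest adjusted p was 0.0595, shared by Degs2 (-3.95 ± 0.23) and, among others, by Pzp, Henmt1, Ugt1a1, the clone 5830411N06Rik and an Ensembl gene without a symbol, whose differences rest on signals not above background in 1 or both sexes. For Prlr the difference was 4.74 (adjusted p = 0.239), with 1 of 2 male EGFP+ arrays well above background. With the mouse as a random block over 6 groups, 439 genes passed.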

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

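Of the tests in this part, the 2 on the value table, the one on the share of proximal tubule in male mice and the rise over each mouse's own EGFP- level were chosen only after the results were seen.

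In 20 of 339 groups of 4 arrays, 1 array lay apart from the other 3, with a gap to the nearest of more than 0.83 of the group's range, and chance gives about 1 in 20 groups, or 16.95. In EGFP- tubules mouse 4 was lowest for Papss2 (0.987), Slc12a1 (0.859), Sostdc1 (0.859), Ppp1r1a (0.851), Oxgr1 (0.838), Des (0.838) and Ppp1r1b (0.835), and highest for Cox7b (0.841). In ALL tubules mouse 4 was lowest for Tyrobp (0.875), Pkm (0.870), Cd52 (0.867), Scnn1a (0.840) and Hsd11b2 (0.832), and mouse 2 highest for Ppp3cb (0.834). In EGFP+ tubules mouse 3 was highest for Trpv6 (0.906), Hba-a1 (0.887), Idh3a (0.851) and Ppp1r1a (0.849), mouse 4 lowest for Sulf1 (0.878) and mouse 1 lowest for Calb1 (0.831). The arrays of mouse 4 hold 13 of these values in ALL and EGFP- tubules, and they were the dimmest, with 75th percentiles of 922 and 1007. No explanation of these was tested.

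The authors' value table holds, under each fraction's heading, the values of another fraction of the same mouse. The columns matched the scanner files under a single shift of 1 fraction in 4 of 4 mice, so the table's columns may have been shifted by 1 fraction within each mouse. The other reading, that the scanner files carry the wrong fraction names and the table's headings are right, would place the total fraction outside the 2 sorted ones. Of 2738 genes differing at least 4-fold between the sorted fractions under those headings, the total fraction lay between them for 5.55%, against 94.5% of 3128 genes under the scanner files' names. No biological explanation was tested.

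Proximal tubule genes stood higher on the EGFP+ array of mouse 2 than on the other EGFP+ arrays, by 1.05 on the log2 scale. Carry-over of all kinds of EGFP- tissue in equal share would have raised podocyte genes alike. Their excess over the other EGFP+ arrays was -4.42% of the proximal tubule list's (-0.135 against 3.07 percent of the EGFP- level), a measure that also moves with the level of a tissue in each mouse. Over each mouse's own EGFP- level, podocyte genes too were highest in mouse 2 (2.72%, against 1.81%, 1.51% and 1.49% in mice 1, 3 and 4). That rise over the mean of the other mice was 1.12 (SD of the others 0.18), against 2.83 (0.77) for proximal tubule, 10.1 (0.98) for smooth muscle and stroma, 3.69 (2.54) for endothelium, 1.42 (13.8) for leukocytes and -0.67 (0.66) for erythroid cells. For collecting duct principal cells the rise was 0.32 (3.14) and for intercalated cells 36.0 (23.9). Over members well above background on all EGFP+ arrays it was 0.90 (0.39) for podocytes, 2.80 (0.81) for proximal tubule and 5.96 (3.56) for smooth muscle and stroma. There it was 3.30 (8.32) for leukocytes and 7.58 (3.71) for collecting duct principal cells. Podocytes and proximal tubule moved apart by more than their spread in both sets, smooth muscle and proximal tubule only with dim members kept. The gap between podocytes and proximal tubule argues against equal shares as the whole cause, but not against some carry-over. A scaling difference of that array would have moved DCT genes too, and their median deviation was -0.13. By the first measure the excess in mouse 2 was 13.3 for intercalated cells, 3.67 for collecting duct principal cells, 2.02 for endothelium, 1.88 for smooth muscle and stroma, -0.070 for leukocytes and -0.95 for erythroid cells. Carry-over of some tissues in unequal share was not tested and stays open, as does a difference by sex, since mouse 2 is male.

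More genes differed by sex in EGFP- tubules (1273) than in EGFP+ tubules (172), in a fit without a term for the mouse. Signals near the background in EGFP+ tubules would leave no such gap among bright genes. Genes well above background on all 12 arrays were fitted and adjusted on their own, so their counts are not parts of those above. Among 7907 of them at least as bright in EGFP+, 569 differed in EGFP- and 5 in EGFP+, a ratio of 113.8. Among 5406 dimmer in EGFP+, 918 and 138 differed. A larger share of proximal tubule in the EGFP- tubules of the male mice would lower the other lists there. Of 10 lists of other segments and cell types, 6 were below both females in both males and all 10 medians were negative, while the proximal tubule median was higher by 0.29. This leaves that share undecided, and a dependence of sex differences on the tubule segment may stand beside it. When that dependence was tested in limma, 0 genes passed, with 2057 at an unadjusted p under 0.05 against 853.5 expected without differences. That test found 0 of 50 simulated genes even at 8-fold, so its count of 0 carries no weight.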

How the results depend on the processing

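Of the tests in this part, those on the value table matched by its values, those with 6 groups and slide as a block, those on lists with slide as a block, those on all tested members of a list and those on the share with genes of 1 direction were chosen only after the results were seen, as was the use of the value table as headed for the lists and the share.

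With the mouse as a block, 113 of 113 results for named genes in the fraction comparisons kept their call, with a gene counted in each comparison that names it. The counts of genes and lists stayed within 1.5 times the reported ones. The list calls it changed are given in the report, and it changed no other. In the simulated data that fit made 11 false calls among 157. The gene counts for EGFP+ against EGFP- other than the 2-fold minimum and the value table as headed ran from 7742 to 14631, the highest with every probe on its own, and those for EGFP+ against ALL from 7348 to 13931. Without 1 mouse they ran from 8466 to 9517 and from 7969 to 8837, and without 1 array from 9237 to 9577 and from 8688 to 9222. Median centring, quantile normalization with and without normexp, an intensity trend and sex as a covariate kept the direction of every named gene of the fraction comparisons. A minimum of 2-fold left 5584 genes for EGFP+ against EGFP- and 5152 for EGFP+ against ALL, by its own construction, and ended the calls of Slc12a1, Ppp3cb and Dnajc14.

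For ALL against EGFP- the count was 132 with only the 2 fractions compared, which leaves fewer arrays to estimate the spread, and ran from 92 to 324 when a mouse or an array was left out. Among the lists for this comparison, thick ascending limb passed with no filter on dim probes (0.0159) and without mouse 2 (0.00325), tubular injury with no filter (0.0309) and without mouse 4 (0.0252), and erythroid without mouse 3 (0.0287). Proximal tubule did not pass with normexp and quantile normalization (0.0969), quantile normalization (0.272), no filter (0.360) or without mouse 1 (0.185). With the value table matched by its values, thick ascending limb (0.0229), tubular injury (0.0472) and the aldosterone pathway (0.0472) passed and glycolysis did not (0.0819). For EGFP+ against EGFP- and against ALL the matched table ended the call of glycolysis (0.0725 and 0.0638), and the female-higher list passed with that table (0.0438 and 0.0400) and with no filter (0.0349 and 0.0280), and for EGFP+ against EGFP- without mouse 1 (0.0416). With all tested members of a list in place of those with a value on all arrays, glycolysis did not pass for EGFP+ against EGFP- (0.0591) or ALL (0.0744), the female-higher list did for both (0.0353 each), and thick ascending limb passed for ALL against EGFP- (0.0142). For male against female mice 12 lists passed in place of 9, and glycolysis did not (0.535). With an estimated correlation between genes, 1 list was left for EGFP+ against EGFP-, 0 for EGFP+ against ALL and 3 for ALL against EGFP-. The share of EGFP+ tubules in the total fraction ran from 8.74% to 11.7% without 1 mouse, was 14.1% over the genes higher in EGFP+ and 5.55% over the lower ones, and the cause was not tested.

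For male against female mice the count was 1473 with 6 groups and the mouse as a random block, 3248 with 6 groups and slide as a block, 933 with normexp and quantile normalization, 429 with probes well above background on all 12 arrays, 33 with no filter on dim probes, and 12 to 51 without 1 mouse. The fits with 6 groups take the fractions of a mouse as separate values, and the one with slide has no term for the mouse. Without a mouse 1 sex has a single mouse, assumed to vary like the others. The cause was not tested. For the dependence of the fraction difference on sex it was 439 with the random block, 341 with normexp and quantile normalization, 8 with quantile normalization and 60 with probes well above background on all 12 arrays, against 0 in the report. Without a filter on dim probes, 576 genes differed by sex in EGFP- and 705 in ALL tubules, and the cause was not tested. Of 135 results for named genes, with a gene counted in each comparison that names it, 126 kept their call with no filter. The other 9 did not, all but Fos from the tests of sex. Signal over background limits the comparisons for the 1003 genes not well above background in EGFP+, the 395 in EGFP- and the 62 in ALL tubules.

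With the columns of the value table as headed, results reversed because the columns hold other fractions, as the table matched by its values shows: it gave 9995 genes for EGFP+ against EGFP-, 9618 for EGFP+ against ALL and 232 for ALL against EGFP-, and as headed 9618 for EGFP+ against EGFP-, 232 for EGFP+ against ALL and 9995 for ALL against EGFP-, with 15 lists for the first and 15 for the last and a share of 109%. The log2 differences for EGFP+ against EGFP- as headed turned negative for these genes. They were Slc12a3 -3.03, Sall3 -3.75, Prox1 -3.72, Abca13 -3.45, Cwh43 -3.34, Sfrp1 -3.26, Prom2 -3.23, Batf3 -3.23, Perm1 -3.37, Vstm2a -3.38 and Ptgfr -3.39. Next came Uroc1 -3.08, Pvalb -3.55, Sox9 -3.86, Hmgcll1 -3.75, Ank2 -3.83, Mapk10 -3.55, Trpm6 -3.76, Trpv6 -2.73, Slc8a1 -2.61, Calb1 -1.61 and Atp6v1b1 -1.61. Next came Oxgr1 -1.25, Casr -2.88, Sostdc1 -2.59, Ier3 -2.98, Fos -1.13, Ppargc1a -1.51, Cox7b -0.94, Idh3a -1.04, Pkm -2.81, Pfkp -2.77 and Hk1 -2.37. Next came Kcnj1 -2.05, Scnn1a -2.41, Ppp1r1a -2.65, Ppp1r1b -2.09, Ppp3cb -0.60, Tfap2b -3.03, Esrrb -3.04, Slc12a1 -0.84 and Umod -1.54. They turned positive for the following. These were Ptpro 6.49, Shisa3 6.35, Sfrp2 6.33, Myom2 6.26, Nphs1 6.13, Chst1 6.19, Itga8 6.04, Gja5 6.12, Ablim3 5.96, Synpo 5.90, Sulf1 5.77 and Plat 5.86. Then came Rarres1 6.81, Papss2 5.41, Ggt5 6.02, Nebl 5.68, Igh 6.90, Fxyd4 4.16, Aqp4 3.30, Aqp3 3.41, Hmx2 1.59, Cldn10 4.93, Slc5a12 5.34 and Slc5a2 5.28. Then came Slc13a1 5.21, Wt1 6.73, Cldn5 5.63, Ehd3 3.80, Eng 3.89, Pdgfra 5.40, Des 4.91, Pdgfrb 4.81, Lyz2 4.62, Tyrobp 4.13 and Cd52 3.59. Then came Hbb-bt 5.37, Hba-a1 5.20, Alas2 5.02, Myc 4.38, Havcr1 4.94, Vcam1 3.76, Acsm1 5.09, Acsm2 4.38, Ehhadh 2.40, Slc2a5 5.26, Slc2a2 5.22 and G6pc 4.92. Then came Cyp4a12a 5.31, Slco1a1 5.32, Abcc2 5.36, Hsd11b2 3.09, Hnf4a 5.12, Aqp2 3.36, Slc34a1 4.54 and Lrp2 4.37. For ALL against EGFP- they were Slc12a3 -8.38, Sall3 -7.50, Abca13 -6.56, Cwh43 -6.54, Sfrp1 -6.31 and Dnajc14 1.37.

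The medians of lists as headed were, for EGFP+ against EGFP-, DCT salt and magnesium handling -2.52, late DCT and connecting tubule calcium handling -1.45, collecting duct principal cell 2.85, proximal tubule 4.68, podocyte 5.51, endothelium 2.71, smooth muscle and stroma 2.72 and leukocyte 1.82. Further, erythroid 5.11, oxidative phosphorylation and citrate cycle -0.52, glycolysis -0.57, gluconeogenesis and fructose use 4.05, drug and organic ion handling 4.82, protein phosphatase subunits and inhibitors -0.35, male-higher kidney genes 3.16 and female-higher kidney genes 4.77. For EGFP+ against ALL there was tubular injury -0.083, past camera's threshold as headed (adjusted p = 0.0472, higher) and not in the report's fit (adjusted p = 0.557). For ALL against EGFP- they were DCT salt and magnesium handling -3.40, late DCT and connecting tubule calcium handling -2.41, collecting duct principal cell 3.06, proximal tubule 4.78, podocyte 5.83, endothelium 2.96, smooth muscle and stroma 3.09, leukocyte 1.93 and erythroid 5.37. Further, oxidative phosphorylation and citrate cycle -0.58, glycolysis -0.54, gluconeogenesis and fructose use 4.15, drug and organic ion handling 4.98, protein phosphatase subunits and inhibitors -0.32, nephron transcription factors -0.10, male-higher kidney genes 3.16 and female-higher kidney genes 4.57.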

Other observations

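Of the tests in this part, those on the total fraction and on the probes of Wnk1 were chosen only after the results were seen.

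Transcription factors of the nephron parted EGFP+ from EGFP- tubules in both directions. Lhx1, a factor of the early nephron, was 11.8-fold higher in EGFP+ tubules (3.56 ± 0.11, SE, n = 4 mice), Grhl2, which shapes the epithelium of distal segments, 9.30-fold (3.22 ± 0.21), Mecom 8.26-fold (3.05 ± 0.19) and Sim1 7.88-fold (2.98 ± 0.41). The Iroquois factors Irx3 (-3.17 ± 0.65, with 2 of 4 EGFP+ arrays well above background), Irx1 (-2.38 ± 0.18) and Irx2 (-2.12 ± 0.28) were lower, as was Sim2, by at least 4.66-fold.

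For some genes the probes disagreed. The representative probe of Hspa12a, a member of the heat shock family, was lower in EGFP+ tubules (-3.59), and another probe was higher (2.39). The representative probe of Kalrn, an exchange factor for small GTPases, was higher (3.49), and another was lower (-1.95, adjusted p = 0.00457).

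The probes of Wnk1, a kinase that controls salt transport, also differed in opposite directions. The probe nearest the 5′ end of the gene (120003253 to 120003312 on chromosome 6) was 2.57-fold lower in EGFP+ tubules (-1.36 ± 0.23, adjusted p = 3.4e-04, higher in 0 of 4 mice). From there on, the probes were higher by 3.46, 5.38, 4.41, 5.10 and 4.21, the last at 119890412 to 119890471. A shorter transcript that starts inside the gene may be the one that is higher in EGFP+ tubules: 5 of the 5 probes after the first were higher. A single lower probe of 6 falls at this end by chance in 1 of 6 cases, and a fault of that probe was not tested.

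Every gene past the threshold and higher in ALL than in EGFP- tubules had a higher mean again in EGFP+ than in ALL tubules (237 of 237). Per the design text the EGFP- tubules are those without EGFP and ALL is a total fraction. EGFP+ tubules in ALL thus follow from the sorting itself. The ALL arrays enter both differences with opposite sign, so that chance in them would push the other way.

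Other splits of the same arrays into 4 and 4 gave no count near those of the sorted EGFP+ tubules. For EGFP+ against EGFP- 1 of 35 splits, the real one, gave as many genes (9932, highest other 0), and for EGFP+ against ALL 1 of 35 (9434, highest other 0). Splits that mix the fractions put the fraction difference into the spread, which itself lowers their counts. The arrays are also paired by mouse, so the 35 splits are not equally likely under chance. Among the 8 splits that part each mouse's arrays the real one again stood alone in both (highest other 0), but 8 are too few for a share under 0.05. The splits therefore cannot exclude chance. For ALL against EGFP- 2 of 35 splits gave as many as the real 238, the other being the split by sex with 5747 genes. That split points to a structure of the samples by sex and takes the ALL and EGFP- arrays of a mouse as separate values. It is no instance of chance, so this count cannot decide on chance. Among the 8 splits that part each mouse's arrays the real one stood alone here too, with 0 as the highest other. The count was 348 with the mouse as a block and 328 with sex as a covariate.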
